A study of Mus musculus with 19 samples.

How the data were processed

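RNA from the brains of male mice was measured on 19 single-colour Affymetrix arrays, whose RNA was purified with a column kit and labelled with biotin per the labels' protocols. The arrays fall into 4 groups by the genotype and agent in the labels: 4 of wild-type (wt) mice given placebo, 5 of wt mice given CCI-779, 5 of transgenic SCA3 mice given placebo and 5 of SCA3 mice given CCI-779. The labels call the arrays samples of mice and state nowhere that each came from a separate mouse, so p-values measure the spread between these samples, which may be technical. The wt CCI-779 sample called replicate 1 carries no number in its label.

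The authors deposited 1 table of linear intensity values for all 19 arrays, made with GCRMA per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes between arrays and summarises the probes of each probe set. Its version is not given in the sources used here, nor is any scanner setting, and the probe-level files were not used here. Values ran from 2.26 to 73595 over 45101 probe sets. The design fixed before the data were examined foresaw a log2 transformation if the values were linear, and log2 was taken here with no pseudocount. The 64 control probe sets were kept out of all tests and served only as measures of array quality. Of the other 45037 probe sets, the 20473 (45.5%) with a mean log2 intensity of at least 4 over the 19 arrays were tested.

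Genes were named from the platform annotation given with the series. Of the 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none in that table, and no gene was named from a probe set with several. The Entrez identifiers of 34754 probe sets matched the reference gene table, which changed no symbol. A gene was represented by its tested probe set with the highest mean over all arrays, which gave 10454 genes. Other probe sets of a gene are given where they disagreed. No genome came with the series, so no coordinates are given.

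Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), in 1 fit with 4 group means over all 19 arrays. The fit had 15 residual degrees of freedom and a prior worth 2.59. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets of each contrast, with a threshold of 0.05. The 5 contrasts were SCA3 against wt under placebo, CCI-779 against placebo in SCA3 and in wt, SCA3 against wt under CCI-779, and the interaction of genotype and drug. A standard error (SE) is that of the moderated test, an SD is that between the arrays of a group, and fold changes are on the linear scale.

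Of 50 gene lists fixed before the data were examined, 44 had at least 5 measured genes and were tested with camera, limma's competitive test, at its preset correlation between genes of 0.01. Its p-values were adjusted over the 44 lists of a contrast. The calls were repeated with a correlation estimated from the data, under which no list passed in any contrast, and with fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. The lists named are those of sterol synthesis under SREBP2, fatty acid synthesis, ribosomal proteins, the proteasome, oxidative phosphorylation, synaptic vesicle and transmission, the response to glucocorticoids, autophagy, the mTOR pathway, deubiquitinases, the unfolded protein response, and markers of myelin and oligodendrocytes, microglia, meninges and fibroblasts, endothelium and astrocytes.

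The genes named follow a rule fixed before the data were examined. Atxn3, Prnp and Usp15 were named whatever their values. In each contrast, up to 12 rising and 12 falling genes past the threshold were named by size of change, and where fewer than 10 genes passed, those next in order of p were named as not passed. Of each list that passed, the 4 members with the smallest p were named. Arglu1 and Slc8a1, further probe sets of Usp15 and further list members were chosen after their values were seen. Whether the mouse Atxn3 probe set also measures the transgene was not tested, and it was not used to check a label.

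Correlations between effects were computed across the 10454 genes, which are not independent replicates, with 100 regroupings of the arrays as the range under chance. For effects that share arrays, unchanged groups were simulated and the shared arrays were split. Array measures were compared by exact two-sided permutation tests with adjustment over 10 tests. The alternatives tried were other filters, quantile normalization again, centring of each array on its median, a trended robust variance, array weights, fits on the compared arrays alone, the mean of a gene's probe sets, the replicate number as a block, other thresholds and leaving out each array in turn. The fit was tested on simulated data for 20473 probe sets with known changes. In the simulation of CCI-779 against placebo in SCA3, 62% of 100 probe sets changed by 0.5 (log2) and 91% of 100 changed by 1 were recovered, and 10 of 163 calls were unchanged probe sets. In that of SCA3 against wt under placebo the shares were 53% and 93%, with 4 unchanged probe sets among 150 calls. The number of arrays limits the precision.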

Results

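Gene expression was measured in the brains of male mice given CCI-779 (temsirolimus), a rapamycin ester that inhibits the kinase mTOR, or placebo. The mice were wild type (wt) or carried an SCA3 transgene. Spinocerebellar ataxia type 3 is caused by an expanded polyglutamine stretch in ataxin-3, a deubiquitinase. CCI-779 was injected into the peritoneum at 20 mg/kg, 3 times a week, from 5 weeks of age for 6 weeks, and placebo was injected as often. There were 4 arrays of wt placebo mice and 5 each of wt CCI-779, SCA3 placebo and SCA3 CCI-779 mice. The comparisons address what the transgene changes, what the drug changes in each genotype, and whether the drug effect depends on the genotype.

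The mean intensity of an array lay between 434 and 463. The hybridisation spike-ins, bacterial transcripts added in fixed amounts before hybridisation, were dimmer on the CCI-779 arrays than on the placebo arrays in both genotypes. In SCA3 their mean log2 intensity was 10.21 ± 0.08 (SD, n = 5) under CCI-779 and 11.01 ± 0.18 (SD, n = 5) under placebo (exact permutation p = 0.00794, the smallest this design can give, adjusted 0.0397). In wt it was 9.89 ± 0.25 (SD, n = 5) against 10.77 ± 0.32 (SD, n = 4) (exact permutation p = 0.0159, adjusted 0.0529). The spike-ins added to the RNA before labelling averaged 7.14 against 8.03 in SCA3 and 7.30 against 7.76 in wt, a difference that was not tested. The log2 difference between the 3′ and 5′ probe sets of GAPDH, a measure of RNA integrity, was −0.35 under CCI-779 and −0.52 under placebo in SCA3 (exact permutation p = 0.00794, adjusted 0.0397). In wt the GAPDH values were −0.28 against −0.54 (exact permutation p = 0.0317, adjusted 0.0794), a difference of 0.26 that was 0.12 without wt CCI-779 replicate 1. The 3′ to 5′ difference of actin, the other such measure, averaged 1.28 under CCI-779 and 1.30 under placebo in SCA3 (exact permutation p = 0.873, adjusted 0.873). In wt it was 1.60 against 1.28 (exact permutation p = 0.294, adjusted 0.42). The actin difference was 0.22 in SCA3 without SCA3 CCI-779 replicates 2 and 5 and 0.08 in wt without wt CCI-779 replicate 1. The array of wt CCI-779 replicate 1 had the widest actin 3′ to 5′ difference (2.55) and a first component score of −66.3. SCA3 CCI-779 replicates 2 and 5 had second component scores of −42.4 and −39.2, while the other arrays of their group lay between −2.47 and 1.96.

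**Figure D1:**
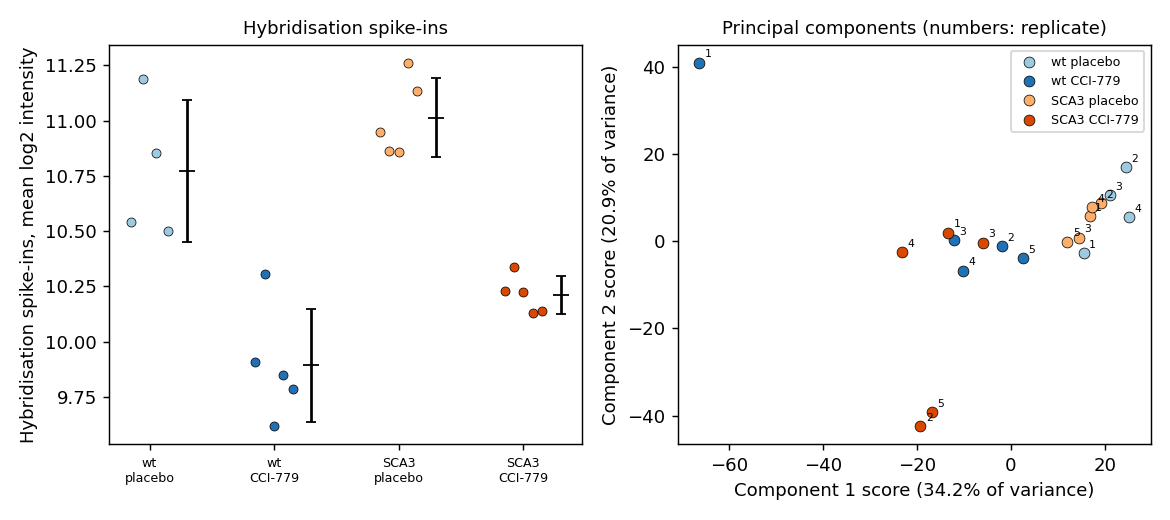
Left, mean log2 intensity of the hybridisation spike-ins on each array (dots, with the group's mean and SD beside them), with all CCI-779 arrays below all placebo arrays. Right, scores on principal components 1 and 2, which hold 34.2% and 20.9% of the variance, with the replicate number at each array.

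Mouse Atxn3 averaged 8.32 ± 0.07 (SD, n = 4) in wt placebo and 8.18 ± 0.18 (SD, n = 5) in SCA3 placebo mice, a difference of −0.14 (SE 0.10, adjusted p = 0.961). Under CCI-779, Atxn3 rose in wt by 0.47 (log2, SE 0.10, adjusted p = 0.00776), while in SCA3 the change of 0.22 did not pass (SE 0.09, adjusted p = 0.13). The interaction was −0.25 (adjusted p = 0.689), and under CCI-779 Atxn3 differed between SCA3 and wt by −0.39 without passing (adjusted p = 0.13). Prnp, the prion protein gene, differed between the genotypes under placebo by 0.00 (SE 0.05, adjusted p = 1). It fell in wt under CCI-779 by 0.18 (adjusted p = 0.039), against a change of −0.13 in SCA3 (adjusted p = 0.0963). Under CCI-779 Prnp differed between SCA3 and wt by 0.05 (adjusted p = 0.624). The call of Prnp was lost without any 1 of wt CCI-779 replicates 1 to 4 and wt placebo replicates 2 to 4 (adjusted p up to 0.0991). Usp15, a deubiquitinase, was measured by 5 tested probe sets that disagreed. The brightest (mean 8.16) showed −0.02 between the genotypes under placebo (SE 0.11, adjusted p = 1), −0.21 under the drug in SCA3 (adjusted p = 0.201) and −0.26 in wt (adjusted p = 0.147). Under CCI-779 this probe set differed between SCA3 and wt by 0.03 (adjusted p = 0.92), and its interaction was 0.05 (adjusted p = 0.947). A dimmer one (mean 6.79) averaged 6.72 ± 0.28 (SD, n = 4) in wt placebo, 6.14 ± 0.21 (SD, n = 5) in SCA3 placebo, 7.07 ± 0.52 (SD, n = 5) in SCA3 CCI-779 and 7.22 ± 0.24 (SD, n = 5) in wt CCI-779 mice. On that probe set of Usp15 the drug effect in SCA3 was 0.93 (adjusted p = 0.00564), the effect in wt 0.50 (adjusted p = 0.129) and the genotype difference −0.59 (adjusted p = 0.709). There SCA3 CCI-779 replicates 2 and 5, which stood apart, were at 7.62 and 7.58, and replicates 1, 3 and 4 at 6.84, 6.43 and 6.87. A further Usp15 probe set (mean 6.93) also rose in SCA3, by 0.54 (adjusted p = 0.0251), with replicates 2 and 5 at 7.55 and 7.47 and the others at 6.85 to 6.96. The tests of these probe sets were not repeated without replicates 2 and 5. The dimmest pair (both with a mean of 5.07) gave 0.57 (adjusted p = 0.0807) and −0.05 (adjusted p = 0.746) in SCA3.

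Between SCA3 and wt mice given placebo, hardly any transcript passed the threshold. In the simulation of this contrast, which gave 150 calls, 53% of probe sets changed by 0.5 (log2) were recovered. With fewer calls the adjusted threshold is stricter, so differences of this size and larger can be missed here. Of 20473 probe sets, 0 were higher and 2 were lower in SCA3 by limma, with 1177 at an unadjusted p under 0.05 where chance gives 1024. A probe set of Arglu1, whose product is an arginine- and glutamate-rich protein that takes part in splicing, fell from 7.28 ± 0.25 (SD, n = 4) to 6.07 ± 0.24 (SD, n = 5), by 1.21 on the log2 scale (SE 0.17, adjusted p = 0.032). A probe set of Slc8a1, a sodium and calcium exchanger, fell from 9.72 ± 0.13 (SD, n = 4) to 8.95 ± 0.18 (SD, n = 5), by 0.77 (SE 0.12, adjusted p = 0.0432). The brightest probe sets of both genes did not differ (Arglu1 −0.03, adjusted p = 1, and Slc8a1 −0.10, adjusted p = 0.988), so by that measure 0 genes passed. On the probe set that differed, Arglu1 was 6.37 ± 0.33 (SD, n = 5) in wt CCI-779 mice. These calls lay near the threshold and were not stable when single arrays were left out. That held for CCI-779 arrays too, which enter this contrast only through the spread. For SCA3 placebo against wt placebo the count was 8 without wt placebo replicate 1 and 1 without wt CCI-779 replicate 1 or SCA3 CCI-779 replicate 1. It was 0 without any 1 of wt CCI-779 replicates 3 and 4, SCA3 CCI-779 replicates 2, 3 and 5, SCA3 placebo replicates 2 to 5 and wt placebo replicates 2 to 4.

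The genes next in order of p did not pass. Gabrg3, a GABA-A receptor subunit, differed by −0.46 (SE 0.08, adjusted p = 0.172), Rusf1 by −0.35 (adjusted p = 0.336), Foxred2 by 0.68 (adjusted p = 0.355), Tle1 by −0.48 and Rab1b by −0.38 (both adjusted p = 0.369). Sidt1 (0.45), Zranb1 (0.60), Nfe2l3 (0.52), Selenon (0.37) and Fam102a (0.25) had adjusted p-values of 0.371 to 0.474. Of the gene lists, the 29 myelin and oligodendrocyte genes had a median of 0.18 with 0 passing singly or adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.854 with an estimated correlation). Their members with the smallest p were Pllp (0.38), Mal (0.37), Fa2h (0.47) and Mog (0.40), with adjusted p-values of 0.678 to 0.818. The 14 fatty acid synthesis genes had a median of 0.11, with Me1 at 0.21, Elovl6 at 0.30, Fads1 at 0.20 and Fasn at 0.12 (camera adjusted p = 0.0304, against 0.063 after quantile normalization, and adjusted p = 0.854 with an estimated correlation). The 41 ribosomal protein genes had a median of −0.03, with Rps6 at −0.14, Rps20 at −0.11, Rpl35 at −0.13 and Rpl13a at −0.09 (camera adjusted p = 0.0271, and adjusted p = 0.854 with an estimated correlation). In both of these lists 0 genes passed, over all genes or adjusted over the list alone, and 74 of 100 splits of the arrays, the real one included, gave as many lists.

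In SCA3 mice given CCI-779, 14 of 30 genes of synaptic vesicles and transmission rose, while 12 of 19 genes of sterol synthesis, 11 of 29 of myelin and oligodendrocytes and 6 of 16 of microglia fell. All 4 lists passed camera at its preset correlation and none did with an estimated one (adjusted p = 0.627 with an estimated correlation for each). Fam163b rose most among the genes past the threshold, from 5.14 ± 0.24 to 8.12 ± 0.90 (SD, n = 5 each), which is 7.94-fold (log2 2.99, SE 0.43, adjusted p = 4.91e-04). Atn1, which encodes atrophin-1, the polyglutamine protein of dentatorubral-pallidoluysian atrophy, rose 5.28-fold (log2 2.40, SE 0.34, adjusted p = 4.19e-04). Gpr34, a receptor of microglia, fell 2.29-fold (log2 −1.20, SE 0.26, adjusted p = 0.00653) and Bdnf, a neurotrophin, fell 1.99-fold (log2 −0.99, SE 0.21, adjusted p = 0.00519). Without SCA3 CCI-779 replicates 2 and 5, which stood apart, Fam163b rose 5.17-fold and Atn1 3.23-fold, and Gpr34 did not pass (−0.75, adjusted p = 0.0568). Of 20473 probe sets, 2094 were higher and 1013 lower by limma, which is 1151 and 637 of 10454 genes, and 657 and 125 probe sets changed by at least 1.5-fold. Of the calls, 67.4% were higher. That share depended on the scaling, at 53.0% after quantile normalization and 44.7% (1587 higher, 1961 lower) after centring each array on its median.

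The other genes that rose most in SCA3 were Mypop (1.84), Rnf208 (1.71), Epn1 (1.55, an endocytic adaptor), Polr2a (2.83-fold, the largest subunit of RNA polymerase II), Adgrg1 (1.48), Unc5a (1.46, a netrin receptor), Trim32 (1.45, a ubiquitin ligase), Slc25a23 (1.43), Apba1 (1.42) and Mapre3 (1.42, a microtubule end-binding protein), with adjusted p-values of 1.48e-04 to 0.00669. For all 12, each of the 5 CCI-779 arrays lay above each of the 5 placebo arrays. The other genes that fell most were Rnf217 (−1.14), Serpinb1a (−1.01), Elovl1 (−0.98, an elongase of very long fatty acids), Gpr17 (−0.96, a receptor of the oligodendrocyte lineage), AA414768 (−0.93), Fdps (−0.93), Vcpkmt (−0.91), Rasgrp3 (−0.88), Tpmt (−0.84, thiopurine methyltransferase) and Dusp19 (−0.82), with adjusted p-values of 4.91e-04 to 0.0236. For 7 of the 12 that fell, all 5 CCI-779 arrays lay below all placebo arrays. Without SCA3 CCI-779 replicates 2 and 5, Mypop was at 1.05 and Epn1 at 0.94. Of the 49 named calls 40 passed without those arrays, and beside Gpr34 those lost were Gpr17, AA414768, Vcpkmt, Cox6b1, Ndufs7, Laptm5, Csf1r and Igfbp2 (adjusted p of 0.0536 to 0.302). With wt CCI-779 replicate 1 left out as well, which enters this contrast only through the spread, AA414768, Vcpkmt, Csf1r and Igfbp2 still did not pass. Gpr34, Gpr17, Cox6b1, Ndufs7 and Laptm5 passed in that setting. Named calls held in 46 of 49 cases when each array was left out in turn, with 3 exceptions. Serpinb1a (adjusted p up to 0.0631) was lost without SCA3 placebo replicate 3, 4 or 5, AA414768 (up to 0.0585) without SCA3 CCI-779 replicate 1 or SCA3 placebo replicate 2 or 4. Igfbp2 (up to 0.107) was lost without SCA3 CCI-779 replicate 2 or 5 or SCA3 placebo replicate 1, 2, 3 or 4.

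**Figure D2:**
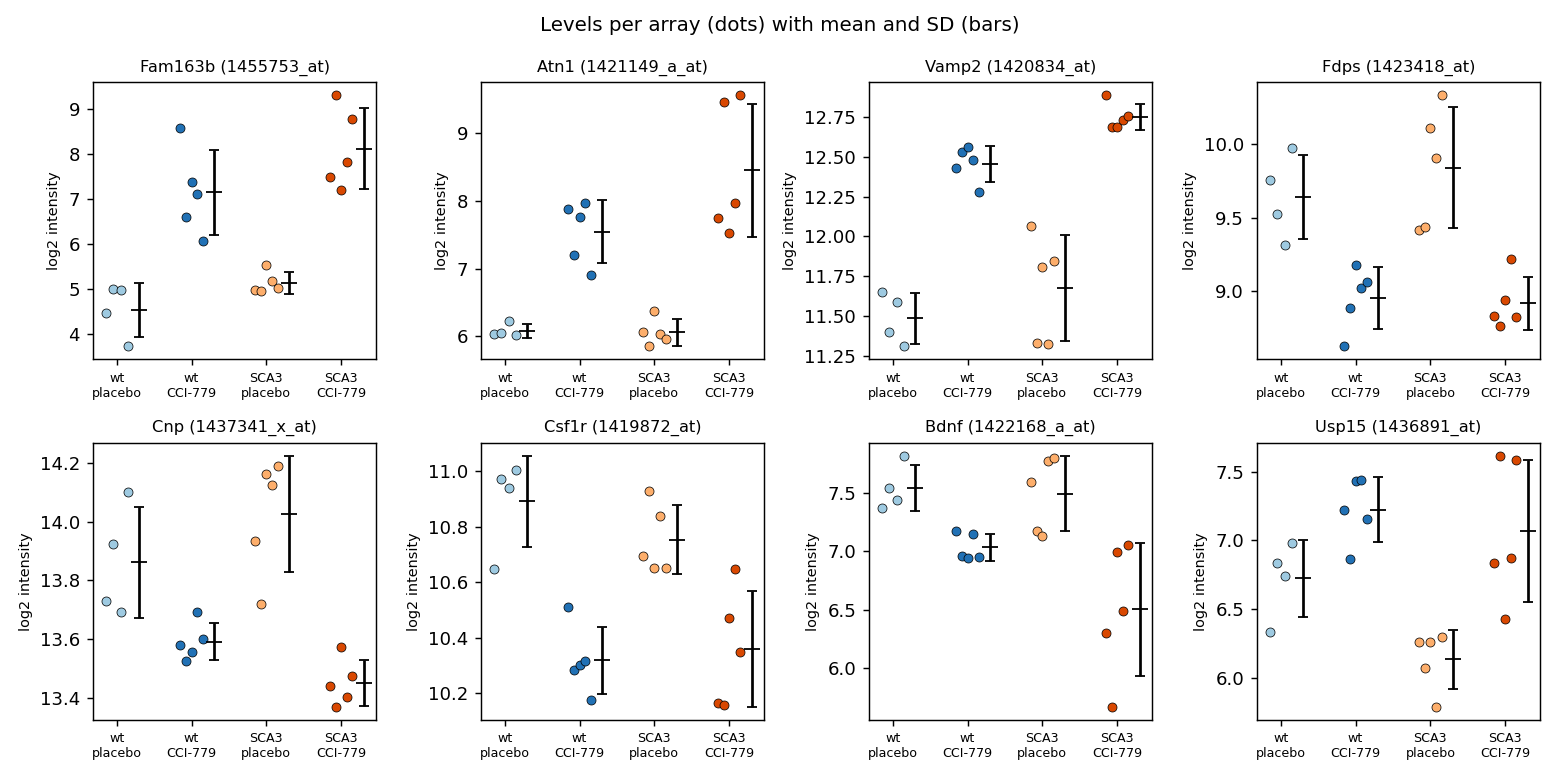
Log2 intensity of 8 genes on each array (dots) by group, with the group's mean and SD beside them, on axes that do not start at 0. Fam163b, Atn1 and Vamp2 rose and Fdps, Cnp, Csf1r and Bdnf fell in SCA3 under CCI-779, and Usp15 is shown by its probe set with a mean of 6.79.

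Of the lists in SCA3, 19 genes of sterol synthesis, the targets of the transcription factor SREBP2, had 1 that rose and 12 that fell (1 and 13 adjusted over the list alone), with a median of −0.40 (camera adjusted p = 2.34e-07, and adjusted p = 0.627 with an estimated correlation). Fdps, which makes farnesyl diphosphate in the mevalonate pathway, fell from 9.84 ± 0.41 to 8.92 ± 0.18 (SD, n = 5 each). Nsdhl (−0.78), Cyp51 (−0.68) and Msmo1 (−0.58), enzymes that turn lanosterol into cholesterol, also fell, and Srebf2, which encodes SREBP2 itself, rose by 0.60 (adjusted p = 0.0391). Of 29 myelin and oligodendrocyte genes, 11 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of −0.28 (camera adjusted p = 2.34e-07, and adjusted p = 0.627 with an estimated correlation). Ugt8a, which makes galactosylceramide, fell by 0.75, Mal by 0.70, Cnp by 0.57 and Olig1, a transcription factor of the lineage, by 0.39. Of 16 microglial genes 6 fell and 0 rose, also adjusted over the list alone, with a median of −0.32 (camera adjusted p = 7.89e-04, and adjusted p = 0.627 with an estimated correlation). Beside Gpr34 these included C1qb (−0.57, complement), Laptm5 (−0.57) and Csf1r (−0.40, the receptor that microglia need to survive).

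Of 30 synaptic vesicle and transmission genes, 14 rose and 1 fell in SCA3 (14 and 4 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 2.74e-04, and adjusted p = 0.627 with an estimated correlation). Vamp2, the vesicle SNARE protein, rose by 1.07 (SE 0.12, adjusted p = 9.64e-05), Syp, synaptophysin, by 1.04, Dlg2, a postsynaptic scaffold, by 0.87 and Syn2, a synapsin, by 0.49, while Cplx1, a complexin, fell by 0.26 (adjusted p = 0.048). Of 41 ribosomal protein genes, 15 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 2.34e-07, and adjusted p = 0.681 with an estimated correlation). Among them were Rps10 (0.36), Rpl19 (0.35), Rpl4 (0.30) and Rps24 (0.23). Of 66 oxidative phosphorylation genes, 14 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of −0.11 (camera adjusted p = 1.50e-04, and adjusted p = 0.832 with an estimated correlation). Cox5b (−0.40), Ndufs7 (−0.35) and Cox6b1 (−0.33) fell, and Uqcrc1, of complex III, rose by 0.36. After centring each array on its median, 30 oxidative phosphorylation genes fell (median −0.17) and 9 ribosomal protein genes rose (median 0.11), and 14 synaptic genes rose and 4 fell (median 0.20). Of 17 meningeal and fibroblast markers, 3 rose (4 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.0404, and adjusted p = 0.627 with an estimated correlation). They were Aldh1a2 (0.58), Bgn (0.61) and Igfbp2 (0.61), and Gjb2 at 0.80 did not pass (adjusted p = 0.0593).

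All of these groups in SCA3 moved together with the dimmer spike-ins (by −0.80) and the altered GAPDH 3′ to 5′ difference (by 0.17) on the CCI-779 arrays. With the spike-in level as a covariate 1 of the 3107 calls was left, as the median change of the called probe sets went from 0.41 to 0.37 and the median SE from 0.10 to 0.18. With the GAPDH difference as a covariate there were 3071 calls, 2324 of them among the 3107, at a median change of 0.39. Without wt CCI-779 replicate 1 that covariate left 0 calls by limma, at a median change of 0.38 and a median SE of 0.20. The count was 1956 without SCA3 CCI-779 replicate 2. Without SCA3 CCI-779 replicates 2 and 5, there were 914 higher and 289 lower probe sets, 7 sterol synthesis, 9 myelin, 4 oxidative phosphorylation and 1 microglial genes fell, and 11 synaptic, 11 ribosomal protein, 3 meningeal and 1 oxidative phosphorylation genes rose. The synaptic median was then 0.14 and the microglial median −0.19, while the sterol synthesis median was −0.52 and the myelin median −0.38. With wt CCI-779 replicate 1 left out as well, 4 microglial genes fell. The meningeal list missed the threshold without wt CCI-779 replicate 1 (camera adjusted p = 0.0539). As many lists passed in 30 of 100 splits of the arrays, the real one included.

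In wt mice given CCI-779, Fam163b rose again most among the genes past the threshold, from 4.54 ± 0.60 (SD, n = 4) to 7.15 ± 0.95 (SD, n = 5), which is 6.11-fold (log2 2.61, SE 0.46, adjusted p = 0.0028). Its wt placebo arrays lay between 3.73 and 5.01, near the filter of 4, so the size of this fold is uncertain. Atn1 rose 2.77-fold (log2 1.47, SE 0.36, adjusted p = 0.0146). Kcnma1, the large-conductance calcium-activated potassium channel, fell 2.25-fold (log2 −1.17, SE 0.32, adjusted p = 0.0277) and Fdps fell 1.61-fold (log2 −0.69, SE 0.18, adjusted p = 0.0213). Of 20473 probe sets, 2002 were higher and 433 lower by limma, which is 1203 and 171 genes, and 536 and 112 probe sets changed by at least 1.5-fold. Of the calls, 82.2% were higher, against 61.3% after quantile normalization and 45.2% (959 higher, 1163 lower) after centring each array on its median, which moved the effects by a median of −0.10. For wt CCI-779 against wt placebo the count was 1349, 1343 and 1355 without wt placebo replicates 2, 3 and 4.

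The other genes that rose most in wt were Zfp316 (1.62), Apc2 (1.61), Npnt (1.57, an extracellular matrix protein), Zfp385a (1.42), Casc3 (1.32, of the exon junction complex), Supt6 (1.27, a transcription elongation factor), Sall2 (1.26), Tns2 (1.26), Cdh19 (1.22, a cadherin) and Polr2a (1.22), with adjusted p-values of 0.00118 to 0.0389. The other genes that fell most were A330076H08Rik (−1.13), Ankrd45 (−0.92), Raly (−0.90, an RNA-binding protein), Fam81a (−0.88), Zfp207 (−0.87), Baalc (−0.83), Arhgef33 (−0.82), Luc7l2 (−0.68), Ninj1 (−0.67) and Grasp (−0.67), with adjusted p-values of 0.00217 to 0.0487. All 5 CCI-779 arrays lay beyond all 4 placebo arrays for 11 of the 12 that rose and 9 of the 12 that fell. Of 42 named calls in wt, 19 held when each array was left out in turn and 23 were lost at least once, 22 without wt placebo replicate 4, 18 without wt placebo replicate 2 and 16 without wt CCI-779 replicate 4. Kcnma1 (adjusted p up to 0.0855) was lost without wt CCI-779 replicate 4 or wt placebo replicate 2 or 4, Fdps (up to 0.0772) without wt CCI-779 replicate 1 or wt placebo replicate 4. Polr2a (up to 0.0738) was lost without wt CCI-779 replicate 1 or wt placebo replicate 2, 3 or 4. Sall2 (up to 0.132) was lost without wt CCI-779 replicate 1, 3 or 4 or wt placebo replicate 2 or 4, and after quantile normalization, and Baalc (up to 0.103) without any 1 of 16 of the 19 arrays. The others were Ankrd45, Arhgef33, Cox6a1, Ctss, Cx3cr1, Grasp, Hsd17b7, Luc7l2, Ndufc1, P2ry12, Prnp, Psma5, Rpl19, Rpl37, Rps10, Rps9, Uqcrc1 and Zfp207.

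Of the lists in wt, 4 of 16 microglial genes fell and 0 rose (9 and 0 adjusted over the list alone), with a median of −0.39 (camera adjusted p = 1.95e-08, and adjusted p = 0.243 with an estimated correlation). P2ry12, a purine receptor of resting microglia, fell by 0.62, Csf1r by 0.57, Ctss by 0.34 and Cx3cr1 by 0.27. Of 19 sterol synthesis genes 2 fell, Fdps and Hsd17b7 (−0.46), and 3 did adjusted over the list alone, with a median of −0.22 (camera adjusted p = 3.31e-06, and adjusted p = 0.847 with an estimated correlation). Mvk (−0.29, adjusted p = 0.05) and Sc5d (−0.39, adjusted p = 0.0718) did not pass. Of 66 oxidative phosphorylation genes 5 fell and 1 rose, also adjusted over the list alone, with a median of −0.05 (camera adjusted p = 1.45e-06, and adjusted p = 0.847 with an estimated correlation). Cox5b (−0.37), Ndufc1 (−0.27) and Cox6a1 (−0.17) were among those that fell, and Uqcrc1 (0.30) was the 1 that rose. Cox6a1 did not pass after quantile normalization. After centring each array on its median Uqcrc1 did not pass, and 19 oxidative phosphorylation, 6 sterol synthesis and 8 microglial genes fell, with medians of −0.15, −0.32 and −0.49.

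Qdpr (−0.24) was the 1 of 29 myelin and oligodendrocyte genes that fell in wt, also adjusted over the list alone, and the list's median was −0.09 (camera adjusted p = 5.40e-04, and adjusted p = 0.847 with an estimated correlation). Ugt8a (−0.40), Opalin (−0.43) and Cnp (−0.27) did not pass. Psma5 (−0.31) was the 1 of 36 proteasome genes that fell, and adjusted over the list alone 0 did, with a median of −0.05 (camera adjusted p = 0.00187, and adjusted p = 0.847 with an estimated correlation). Psmc2 (−0.18), Psmb3 (−0.29) and Psmb5 (0.27) did not pass. Of 41 ribosomal protein genes 4 rose, namely Rpl37 (0.36), Rpl19 (0.26), Rps9 (0.25) and Rps10 (0.25), and 13 did adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0201, and adjusted p = 0.847 with an estimated correlation). After centring each array on its median none of these 4 passed and the list's median was 0.03 (camera adjusted p = 0.339). Itm2a (−0.41) was the 1 of 15 endothelial markers that fell, also adjusted over the list alone, with a median of −0.02 (camera adjusted p = 0.0436, and adjusted p = 0.847 with an estimated correlation), and Tek (0.28), Cldn5 (−0.67) and Egfl7 (−0.21) did not pass. After centring, 5 myelin genes (median −0.19) and 6 proteasome genes (median −0.15) fell, and the endothelial median was −0.13 (camera adjusted p = 0.125). The 30 synaptic genes missed the list threshold by camera (median 0.30, camera adjusted p = 0.058, against 0.00336 after quantile normalization and 0.0151 after centring) and passed it by fry. Of them 14 rose and 0 fell (16 and 3 adjusted over the list alone, 9 and 3 after centring), among them Nlgn2, a neuroligin of inhibitory synapses (1.21), Vamp2 (0.97) and Syp (0.88).

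In wt as well these groups moved together with the spike-ins (by −0.88) and the GAPDH difference (by 0.26, or 0.12 without wt CCI-779 replicate 1), and with the spike-in level as a covariate 0 of the 2435 calls were left by limma. The median change of those probe sets went from 0.43 to 0.36 and their median SE from 0.11 to 0.19. With the GAPDH difference as a covariate there were 770 calls, 665 of them among the 2435, at a median change of 0.37, and 29 without wt CCI-779 replicate 1, at a median change of 0.41 and a median SE of 0.16. Leaving out wt CCI-779 replicate 1 alone, 9 oxidative phosphorylation, 3 proteasome and 1 sterol synthesis genes fell and 1 ribosomal protein gene rose. The myelin median was then −0.05 and the endothelial median −0.08, and the synaptic list passed (camera adjusted p = 0.0236). In wt, 8 oxidative phosphorylation and 2 proteasome genes fell without SCA3 CCI-779 replicates 2 and 5, which also set the spread here. As many lists passed in 40 of 100 splits of the arrays, the real one included.

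The drug effects in the 2 genotypes, which share no arrays, ran in parallel. The CCI-779 arrays of both genotypes also had dimmer spike-ins (by −0.80 in SCA3 and −0.88 in wt). A difference in hybridisation or RNA integrity common to them could give the same parallel. Regrouping within genotypes cannot tell it from the drug. Across 10454 genes, which are not independent replicates, the log2 changes in SCA3 and wt correlated at r = 0.706 (rho = 0.667). None of 100 regroupings of the arrays within genotypes gave as large a value (permutation p = 0.0099, the smallest they can give, range −0.472 to 0.379). Of the probe sets called higher, 1035 were called in both genotypes, where independent lists would share 205, and of those called lower 173 were, where independent lists would share 21.4. Only 1 was called in opposite directions. Both calls use the same variance estimate of a probe set, which by itself favours shared calls, so the counts for independent lists are only a rough baseline. Of the 3107 probe sets called in SCA3, 94.7% had the same sign in wt, and of the 2435 called in wt, 94.8% had the same sign in SCA3. Over all 10454 genes the share was 72.1%.

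**Figure D3:**
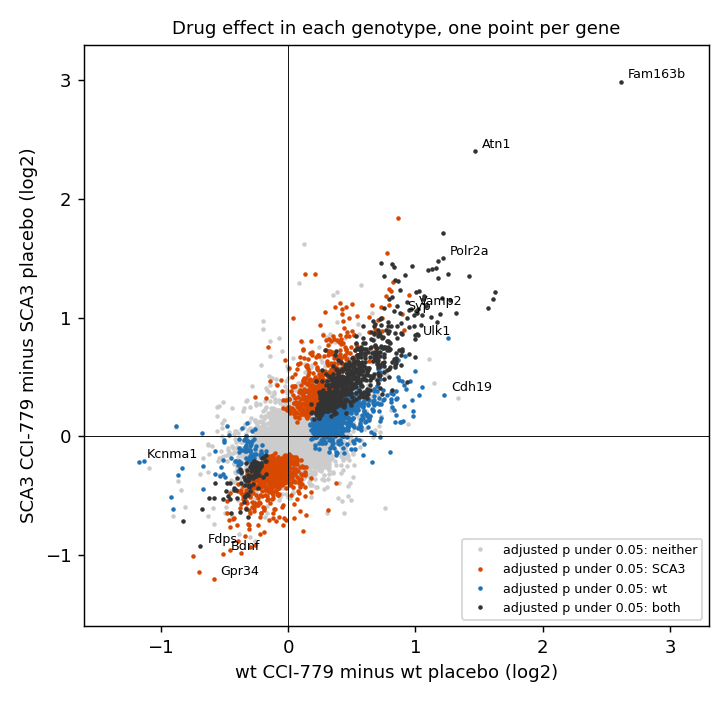
Log2 change under CCI-779 in wt (horizontal) and in SCA3 (vertical), one point per gene for 10454 genes, coloured by the genotype in which the gene passed the threshold. Fam163b and Atn1 lie far up in both, Kcnma1 passed in wt, and Bdnf and Gpr34 passed in SCA3.

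No difference between the drug effects passed for a single gene. For the interaction, 0 probe sets passed by limma, with 1573 at an unadjusted p under 0.05 where chance gives 1024, and a smallest adjusted p of 0.37. Nearest among the genes were Fubp3 (−0.77, SE 0.16), Fam81a (0.97), Ybx3 (−0.42), Haus3 (−0.74), Mcc (−0.75), Cep290 (−0.87), Hadhb (−0.35) and Csgalnact2 (−0.47), all with an adjusted p of 0.419, then Acad8 (−0.42) and Zfx (−0.44) with 0.517. For Kcnma1, Bdnf and Gpr34 as well, a difference in drug effect between the genotypes was therefore not shown. The 29 myelin and oligodendrocyte genes had a median interaction of −0.26 (camera adjusted p = 0.044, and adjusted p = 0.932 with an estimated correlation), with Mal at −0.55, Myrf at −0.44, Olig1 at −0.33 and Ndrg1 at −0.27. The 41 ribosomal protein genes had a median of 0.06 (camera adjusted p = 0.00125, and adjusted p = 0.932 with an estimated correlation), with Rpl4 at 0.15, Rps18 at 0.14, and Rps24 and Rps29 at 0.09. In both lists 0 genes passed, over all genes or adjusted over the list alone, and 85 of 100 splits gave as many lists.

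Between SCA3 and wt mice that both received CCI-779, 2 of 20473 probe sets were lower in SCA3 and 0 were higher by limma, with 3163 at an unadjusted p under 0.05. Ybx3, a cold-shock domain protein that binds RNA, was 10.04 ± 0.05 in SCA3 and 10.54 ± 0.06 in wt (SD, n = 5 each), a difference of −0.50 (SE 0.07, adjusted p = 0.014). Fubp3, which binds single-stranded DNA and RNA, was 8.32 ± 0.25 against 9.10 ± 0.15 (SD, n = 5 each), a difference of −0.78 (SE 0.11, adjusted p = 0.0207). Each SCA3 array lay below each wt array for both genes. Under placebo the genotypes differed by −0.08 for Ybx3 and −0.01 for Fubp3. Without wt CCI-779 replicate 5 or SCA3 CCI-779 replicate 5 neither gene passed (count 0), and Fubp3 was also lost without wt CCI-779 replicate 4 or SCA3 CCI-779 replicate 1, with adjusted p-values of up to 0.0706 for both genes. Without SCA3 CCI-779 replicates 2 and 5 neither passed (both adjusted p = 0.203). For SCA3 CCI-779 against wt CCI-779 the count was 8 without SCA3 CCI-779 replicate 3, 5 without wt CCI-779 replicate 1 or 2, and 1 without SCA3 CCI-779 replicate 1.

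Next in order of p, without passing, were Uty (−0.66) and Rab9b (−0.63), both with an adjusted p of 0.0857, then Socs5 (−0.37), Klhl4 (−0.67), Prss23 (−0.78), Haus3 (−0.61), Foxp4 (0.45) and Ythdf3 (−0.29), all with 0.111. The 30 synaptic genes had a median of 0.05 (camera adjusted p = 0.00178, and adjusted p = 0.714 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone. Cplx2 was at 0.38, Syn2 at 0.23, Slc17a7 at 1.24 and Shank3 at 0.30, none of which passed. Slc17a7 was at 0.28 without SCA3 CCI-779 replicates 2 and 5, and the synaptic median was 0.03 without wt CCI-779 replicate 1. The 19 genes that respond to glucocorticoids had a median of −0.34 (camera adjusted p = 0.0395, and adjusted p = 0.999 with an estimated correlation), with Slc2a1 at −0.50, Klf9 at −0.27, Sult1a1 at −0.70 and Htra1 at −0.25. Their median was −0.22 without SCA3 CCI-779 replicates 2 and 5 (camera adjusted p = 0.047). The 17 meningeal and fibroblast markers had a median of 0.09 (camera adjusted p = 0.0395, against 0.0676 after quantile normalization and 0.0572 after centring, and adjusted p = 0.999 with an estimated correlation), with Gjb2 at 0.91, Col1a1 at 0.30, Bgn at 0.34 and Ptgds at 0.10. This call was also lost without wt CCI-779 replicate 1 (camera adjusted p = 0.198). In both of these lists 0 genes passed, over all genes or adjusted over the list alone, and 46 of 100 splits gave as many lists.

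Across 10454 genes, which are not independent replicates, the genotype differences with and without drug correlated at r = 0.20 (rho = 0.218), and 12 of 100 regroupings of the arrays within treatments gave as large a value (permutation p = 0.129). Whether the drug turned back the genotype difference was examined by correlating the drug effect in SCA3 with the genotype effect under placebo, which share the SCA3 placebo arrays. Across genes r was 0.0605 (rho = 0.0736), while unchanged groups sharing those arrays gave a mean of −0.470 in simulation (range −0.512 to −0.405). The covariance was 0.00206 against −0.00767 in simulation, and with the SCA3 placebo arrays split between the effects r averaged 0.175 over 10 splits (0.0243 to 0.294). The value without SCA3 placebo replicate 1 was −0.0425, without wt placebo replicate 2 it was −0.0385 and without wt placebo replicate 4 it was −0.0097. All values with 1 array left out (−0.0425 to 0.164) lay above the simulated range. That range was drawn without a drug effect and without correlation between genes, so it may be too narrow. Lying above it cannot decide whether the drug turned back the genotype difference. The 2 probe sets that differed by genotype under placebo were selected on the placebo arrays that both drug effects use, which by itself favours a rise in SCA3 and a fall in wt. With that limit, the probe set of Slc8a1 rose in SCA3 under CCI-779 by 0.44 (adjusted p = 0.014) and fell in wt by 0.39 (adjusted p = 0.0381). That of Arglu1 did not change in SCA3 (0.24, adjusted p = 0.342) and fell in wt by 0.91 (adjusted p = 0.0037).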

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

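The fits with a covariate and the tests on array quality and on single arrays were chosen after the arrays' values were seen, and the splits of the arrays were planned.

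The probe sets that differed between CCI-779 and placebo arrays outnumbered those of every other split drawn. In SCA3 1 of 100 splits, the real one, gave as many (3107, highest other 43). In wt 1 of 100 did (2435, highest other 1530, from the split that moved only wt CCI-779 replicate 5 to the side of the placebo arrays). That is the smallest share these splits can give, so chance is an unlikely source for both if the samples are independent. Against the drug as the source, the hybridisation spike-ins, which hold no mouse RNA, differed too, by −0.80 in SCA3 and −0.88 in wt, and all 10 CCI-779 arrays lay below all 9 placebo arrays. If a hybridisation difference were the source, the slopes on the spike-ins within groups could predict the drug effects, and the correlation of predicted and observed changes was 0.10 in SCA3 and 0.104 in wt, while for RNA integrity (GAPDH, without wt CCI-779 replicate 1) it was 0.141 and 0.0288, all within the range of shuffled arrays. With GAPDH as a covariate 3071 calls were made in SCA3 and 770 in wt, but 0 and 29 without wt CCI-779 replicate 1, where the median change went from 0.41 to 0.38 in SCA3 and from 0.40 to 0.41 in wt and the calls ended because the median SE rose from 0.10 to 0.20 and from 0.10 to 0.16. The drug and a difference in hybridisation or RNA integrity cannot be told apart, since the spike-ins and GAPDH run with the drug, while actin, the other measure of integrity, averaged 1.28 against 1.30 in SCA3 but was 0.22 higher under CCI-779 without replicates 2 and 5.

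SCA3 CCI-779 replicates 2 and 5 stood apart from the rest of their group, with actin 3′ to 5′ differences of 0.96 and 0.88 and 18S levels of 5.73 and 5.63. For another makeup of brain regions in the tissue taken, the largest median difference of a region list reached in both arrays was 0.285, for the 5 markers of serotonin and noradrenaline neurons. For a difference in RNA preparation followed by the 18S signal, the correlation of predicted and observed differences was 0.214, within the range of shuffled arrays. Both explanations stay open, because the region value lay between the limits set for its test and the 18S correlation within its shuffled range. With 2 arrays and 5 markers these tests are also weak. No biological explanation was tested as the labels give none.

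For the other counts, 2 of 100 splits gave as many probe sets as SCA3 against wt under placebo (2, highest other 7), fewer than the limit set beforehand. The splits still cannot exclude chance there. The count is 2 probe sets near the threshold (adjusted p of 0.032 and 0.0432 by limma), and leaving out single arrays often removed both. Whether the split with several times the real count follows a structure of the samples was not tested. Nor can chance be excluded for SCA3 against wt under CCI-779, where 8 of 100 splits gave as many (2, highest other 87, where such a structure was not tested either). For the interaction the splits test nothing, since the real count is 0 and all 100 must reach it (highest other 1115). The split with 1115 exchanged the drug labels of all 10 SCA3 arrays and of replicate 4 in both wt groups, and exchanging the SCA3 labels makes the interaction nearly the sum of the drug effects, so its calls are no sign of another structure. Chance could not be excluded for any count of gene lists. The splits with as many lists were 74 of 100 for SCA3 against wt under placebo (3, highest other 16), 30 for the drug in SCA3 (7, highest other 16), 40 for the drug in wt (7, highest other 15), 46 for SCA3 against wt under CCI-779 (3, highest other 9) and 85 for the interaction (2, highest other 17). Between the genotypes, the drug effect differed by the list test for ribosomal proteins (median interaction 0.0569) and for myelin and oligodendrocyte genes (−0.26) at the preset correlation alone. No member passed singly, and the difference was lost for both (adjusted p = 0.932 with an estimated correlation).

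Single arrays lay far from the rest of their group in 41 of 572 groups of values of the 143 named genes (7.17%), where chance alone gives about 1 in 20. The array of wt CCI-779 replicate 1 did so in its actin (2.55) and GAPDH (0.28) 3′ to 5′ differences and its mean correlation with its group (0.968), and SCA3 placebo replicate 4 in GAPDH (−0.47). All gene values here are log2 intensities. In wt CCI-779 replicate 1 they were 6.66 for Rusf1, 14.8 for Rpl13a, 5.96 for Rasgrp3, 4.38 for Dusp19, 14.5 for Cox6a1, 8.53 for Myrf and 7.66 for Usp15. In wt CCI-779 replicate 2 they were 5.90 for Gabrg3, 5.90 for Rnf217 and 6.34 for Tpmt, and in replicate 4 the level of Cep290 was 5.94. Among wt placebo arrays, replicate 1 had 10.23 for Fam81a, 11.33 for Htra1 and 13.97 for Prnp, and replicate 2 had 5.21 for Sall2. Replicate 3 of wt placebo had 6.22 for Atn1 and 12.18 for Psmc2, and replicate 4 had 9.67 for Pllp, 8.29 for Apba1 and 8.63 for Cldn5. Among SCA3 placebo arrays, replicate 1 had 8.59 for Cx3cr1 and 12.39 for Hadhb, replicate 2 had 5.63 for Tek and replicate 3 had 7.31 for Selenon. Replicate 4 of SCA3 placebo had 11.49 for Psma5, 9.40 for Klhl4 and 15.23 for Rps29, and replicate 5 had 9.46 for Fam102a and 8.74 for Grasp. Among SCA3 CCI-779 arrays, replicate 1 had 6.99 for Cldn5, 5.49 for Haus3 and 12.02 for Slc2a1, and replicate 2 had 5.04 for Tpmt, 5.20 for Arhgef33, 10.23 for Rpl37 and 7.88 for Fubp3. Replicate 3 of SCA3 CCI-779 had 8.48 for Cx3cr1, replicate 4 had 8.97 for Baalc and 6.34 for Mcc, and replicate 5 had 10.05 for Fa2h and 6.01 for Mvk.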

How the results depend on the processing

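The fits without SCA3 CCI-779 replicates 2 and 5, without these and wt CCI-779 replicate 1, and with a covariate were chosen after seeing the data, and the other alternatives were planned. Counts are of probe sets unless lists are named, and the cause of a change was not tested unless stated.

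Of the planned settings, those with a stricter filter, arrays centred on their median and a trended variance kept every total of probe sets within 1.5 times. Centring moved the directions, from 2094 higher and 1013 lower to 1587 and 1961 for the drug in SCA3 and from 2002 and 433 to 959 and 1163 in wt, and the count for the interaction was 0 in all settings. SCA3 against wt under placebo gave 1 probe set without a filter, after quantile normalization and with only the compared arrays. The drug in wt gave 1584 without a filter, as more probe sets were tested, and 1364 with only the compared arrays, where fewer arrays set the spread. SCA3 against wt under CCI-779 gave 1 without a filter, with only the compared arrays and at 1.5-fold or more, and 6 with array weights and at an adjusted p under 0.1. At 1.5-fold or more the drug gave 782 in SCA3 and 648 in wt, and at an adjusted p under 0.1 it gave 4046 in wt. By the mean of a gene's probe sets, 1 gene passed in each genotype comparison.

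Leaving out 1 array at a time gave 0 to 8 for SCA3 against wt under placebo, 1956 (without SCA3 CCI-779 replicate 2) to 4048 (without wt CCI-779 replicate 1) for the drug in SCA3, 1343 to 2717 for the drug in wt, 0 to 8 for SCA3 against wt under CCI-779 and 0 for the interaction. For wt CCI-779 against wt placebo the count was 1349, 1343 and 1355 without wt placebo replicates 2, 3 and 4. The lists past the threshold numbered 1 to 9, 6 to 10, 5 to 10, 1 to 4 and 0 to 5 in the same order. Without SCA3 CCI-779 replicates 2 and 5 the counts were 0 under placebo, 1203 for the drug in SCA3 and 0 under CCI-779, with 11, 6 and 5 lists for the drug in SCA3, the genotypes under CCI-779 and the interaction. Without these and wt CCI-779 replicate 1 they were 0 under placebo and 2335 for the drug in SCA3, with 11 and 6 lists for the drug in SCA3 and the interaction.

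With the spike-in level as a covariate, 0 probe sets were left for SCA3 against wt under placebo and 0 under CCI-779. For the drug 1 was left in SCA3 and 0 in wt, because the covariate runs with the drug and the median SE rose. With the GAPDH difference the probe sets numbered 1 under placebo, 3071 for the drug in SCA3, 770 in wt and 5 under CCI-779. Without wt CCI-779 replicate 1, the GAPDH covariate left 0 for the drug in SCA3 (median change 0.38, SE 0.20) and 29 in wt (0.41, SE 0.16).

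Nothing in the labels says that a shared replicate number marks a shared litter, batch or day. The correlation of deviations from the group means over 24 same-numbered pairs ran from −0.307 to 0.29, with 9 over 0.1, and 16 of 48 comparisons were best with their own number, so the numbers were not taken to pair the samples. The fit with the replicate number as a block also left out wt CCI-779 replicate 1, which has no number. It gave 0 probe sets under placebo, 3744 for the drug in SCA3, 1384 in wt and 0 under CCI-779, and 1 list under placebo, where leaving out that array without a block gave 1, 4048, 1713 and 5 probe sets.

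With an estimated correlation 0 lists passed in each of the 5 contrasts. Under fry 0 passed under placebo, 9 for the drug in SCA3 (5 higher, 4 lower), 14 in wt (13 higher, 1 lower), 0 under CCI-779 and 0 for the interaction, against 7 (3 higher, 4 lower) and 7 (1 higher, 6 lower) by camera for the drug in SCA3 and wt. Lists under CCI-779 numbered 6 without a filter. By the mean of probe sets they numbered 1 under placebo, 1 under CCI-779 and 5 for the interaction. The correlation of the drug and genotype effects in SCA3 (0.0605) was −0.00403 without a filter and −0.0425 to 0.164 when 1 array was left out. It was −0.0425 without SCA3 placebo replicate 1, and −0.0385 and −0.0097 without wt placebo replicates 2 and 4. All lay above the −0.512 to −0.405 of simulated unchanged groups, a range drawn without correlation between genes. With 1 array left out the correlation of genotype effects was 0.121 to 0.228 and that of drug effects 0.659 to 0.73. A GCRMA value near the floor of an array carries little signal over background, so no statement is made on the probe sets below the filter.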

Other observations

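Several pathways related to mTOR showed single genes past the threshold under CCI-779 without passing camera as lists. By fry, which does not compare a list with other genes, the autophagy, mTOR pathway, deubiquitinase, glucocorticoid and astrocyte lists passed in wt. The unfolded protein response list passed fry in SCA3. Of all 10454 genes, 1203 rose and 171 fell in wt, and 1151 rose and 637 fell in SCA3. Single calls were thus frequent outside these lists as well. Of 37 autophagy genes, 7 rose and 0 fell in wt (10 and 0 adjusted over the list alone), led by Ulk1, the kinase that starts autophagy and is a substrate of mTOR (8.78 ± 0.30 under placebo, SD, n = 4, and 9.78 ± 0.11 under CCI-779, SD, n = 5, adjusted p = 8.80e-04), with Atg9a at 0.51 and Wipi2 at 0.50. In SCA3 6 rose and 2 fell (7 and 2 adjusted over the list alone), with Ulk1 at 0.82 (SE 0.13, adjusted p = 9.08e-04), Atg9a at 0.58 and Wipi2 at 0.49 rising and Map1lc3b, which encodes an LC3 protein of the autophagosome, at −0.24. The camera adjusted p was 0.31 in wt and 0.511 in SCA3, and the list's median in SCA3 turned from 0.03 to −0.01 after quantile normalization and −0.03 after centring the arrays on their median. After centring, 2 rose and 2 fell in wt, and 3 rose and 4 fell in SCA3 (3 and 3 after quantile normalization). Of 44 mTOR pathway genes, 8 rose and 0 fell in wt (10 and 0 adjusted over the list alone), among them Igf1r (0.84), Akt1 (0.60) and Mtor (0.31), and 6 rose and 3 fell in SCA3, also adjusted over the list alone, among them Akt1 (0.66), Igf1r (0.60) and Rragd (−0.41). The camera adjusted p was 0.752 and 0.511, and the medians of 0.08 and 0.04 turned to −0.02 in both genotypes after centring, where 3 rose and 1 fell in wt. Without wt CCI-779 replicate 1, 4 autophagy and 3 mTOR pathway genes rose and 0 fell in wt, and without SCA3 CCI-779 replicates 2 and 5, 1 and 3 rose and 0 fell in SCA3.

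Of 46 deubiquitinase genes, 8 rose and 0 fell in wt, also adjusted over the list alone, led by Usp11 (0.50), Atxn3 (0.47) and Otud1 (0.38), and 4 rose and 1 fell in SCA3 (3 and 1 adjusted over the list alone), with Usp11 at 0.60, Usp31 at 0.43 and Otud6b at −0.30. The camera adjusted p was 0.557 and 0.778, and the medians of 0.08 and 0.02 turned to −0.02 and −0.04 after centring, where 3 rose and 2 fell in wt and 2 rose and 2 fell in SCA3. Among 22 genes of the unfolded protein response in SCA3, 4 fell and 1 rose, also adjusted over the list alone, with the chaperones Hspa5 (−0.37) and Canx (−0.26) and the retrotranslocation factors Derl2 (−0.36) and Derl1 (−0.30) falling and Dnajb9 (0.20) rising (median −0.15, camera adjusted p = 0.0697), against 5 and 0 after centring. Among 19 genes that respond to glucocorticoids, Fkbp5 (0.96), Sult1a1 (0.81) and Mt2 (0.52) rose in wt, also adjusted over the list alone (median 0.45, camera adjusted p = 0.0629, against 0.00725 after quantile normalization, where 2 rose, and 0.00608 after centring, where 1 rose), while in SCA3 Per1 (1.19) was the 1 that rose, also adjusted over the list alone (median 0.12, camera adjusted p = 0.623). Of 22 astrocyte genes, 6 rose and 0 fell in wt (7 and 0 adjusted over the list alone), with the glutamate transporter Slc1a2 at 0.18 and Atp1b2 at 0.55, and in SCA3 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.557 and 0.748, with medians of 0.06 and 0.05 that turned to −0.05 and −0.01 after centring). After centring 2 astrocyte genes rose and 1 fell in wt (3 and 0 after quantile normalization), and 3 rose and 3 fell in SCA3. Without wt CCI-779 replicate 1, 5 deubiquitinase and 3 astrocyte genes rose in wt, and the glucocorticoid list passed there (camera adjusted p = 0.0187). In SCA3, 2 deubiquitinase genes rose and 1 fell without SCA3 CCI-779 replicates 2 and 5, 3 astrocyte genes rose and 0 fell, and 0 glucocorticoid genes rose. The unfolded protein response in SCA3 then had a median of −0.055, with 4 genes that fell and 1 that rose.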
